A study of Homo sapiens with 31 samples.

How the data were processed

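Per the labels, mononuclear cells were taken from heparin blood over Ficoll, and their total RNA was labelled with Cy5 and hybridised together with Cy3-labelled RNA of a pool of 21 human cell lines, a common reference on all 31 arrays. Per the labels, 16 samples were tolerant, 10 came from grafts undergoing chronic nephropathy and 5 from healthy donors without a transplant. The sample titles number grafts and donors within each group, but beyond this and the blood preparation the labels do not say how the samples were taken. The p-values thus measure the spread between these samples, which may in part be technical. The groups, tests, gene lists, naming rule and 27 alternatives were chosen before the data were examined, and 7 alternatives were added after seeing the data, which makes 34 settings tried.

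Per the file headers, the deposited scanner files hold the mean pixel intensity of each spot in both colours and the median intensity of its local background, made with Feature Extraction. Version 9.5.1.1 had made 13 files of the main design, version 9.5.3.1 the other 14 and version A.7.5.1 the 4 of the second design. Per the file headers, the same files hold the software's log10 ratio of red over green after its own background subtraction and dye normalization, and its quality flags. The deposited processed values of the authors, in the series matrix, were found to be the natural log of red over green. They were set against the software's log ratio of the same array after its conversion from log10 to log2. The slope was 0.691 to 0.705, that of a natural log against a log2, with r from 0.978 to 0.9998 and a lowest value of -4.605. What else the authors did to make them is not given in the sources used here. They were not centred, with column medians from -0.512 to 0.006 on the main design, and their direction was red over green.

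The main design held 45015 spots, 43376 of them not controls, for 41000 probes, and the 4 arrays of the second design carried the same 41000 probes. Background was corrected with normexp at an offset of 50, and each array was normalized by loess with control spots and spots carrying an outlier flag (0.43% of the non-control spots) at weight 0. Spots with an outlier flag were set missing, and spots of the same probe were averaged. The headers name the builds hg17:NCBI35:May2004 and hg18:NCBI36:Mar2006 for the 2 annotation layouts, whose gene names differed in 7019 cells, and the newer layout was used for all arrays. No coordinate is printed. Gene names came from a reference table of GRCh38.p14, for 23958 probes by accession, 2755 by symbol and 1032 by an older symbol, while 2063 kept the name in the file and 11192 had none and were not used. The 106 probes of Y-linked genes, XIST and TSIX were removed before any test. A gene was tested if its red signal was well above background on at least 5 of the 27 arrays, by the software's flag, and it was represented by its probe with the highest mean red signal, which left 16640 genes.

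Each gene's log2 ratio of red over green was fitted in R 4.3.3 with limma 3.58.1, after reading the files with the package data.table of version 1.17.8, with a term for each of the 3 groups and 1 for the extraction batch. The batch was defined by the protocol name written into the file names, a split that equals the software version, since the headers name the same protocol on all 27 arrays. Tests were two-sided with Benjamini-Hochberg adjustment over genes within each comparison, and a gene was called at an adjusted p under 0.05. Residuals had 23 degrees of freedom and the prior added 3.9. Differences are fitted with the batch term, whereas group means ± SD are over the samples as they are, so the 2 need not match. The errors given with differences are standard errors from 1 spread shared by the 3 groups, so they are too small where the healthy group spreads more widely.

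Gene lists were tested with camera of limma at an inter-gene correlation of 0.01 and adjusted over the 26 lists. Camera with the correlation estimated for each list, and fry, were alternatives. The lists were B cells, tolerance genes of earlier kidney studies, plasma cells, pan T cells, naive and central memory T cells, cytotoxic lymphocytes, NK cells, regulatory T cells, monocytes, dendritic cells, neutrophils and their precursors, platelets, red cell precursors, interferon-induced genes, inflammatory cytokines and NF-kB targets, immediate early genes, heat shock genes, hypoxia and glycolysis genes, glucocorticoid-induced genes, TGF-beta signalling, MHC class II presentation, costimulation and checkpoint receptors, proliferation, cytosolic ribosomal proteins, nuclear-coded oxidative phosphorylation, and the 3 genes of the research group's blood assay. Lists shared genes, such as GZMB in the cytotoxic and dendritic lists and KLF6 in the immediate early and assay lists. A list score is the mean of its genes' deviations from their mean over the 27 arrays.

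Named genes were the 10 largest differences in each direction among called genes, or the 3 with the smallest p in a direction where none was called, up to 4 called members of each list, and all members of the 3-gene list. Genes named by an accession or a clone, Y-linked genes, XIST, and genes whose level can report a variant carried by 1 person were left out of the names. Between the graft groups, the members with the smallest p of each list called by camera were added after their values were seen. Genes named for a count of few calls under another setting, and the stretch of zinc finger genes, were also chosen after their values were seen. Values of single genes are those of 1 probe. Some genes named by this rule had other detected probes, compared by group means without the batch term. At least 1 of these went in the opposite direction for 2 of 15 such genes between the graft groups. The same held for 10 of 35 in tolerant and 8 of 38 in chronic nephropathy against healthy samples.

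In a self-test, 200 genes were changed in data simulated from the residual spread of the 16640 genes. For tolerant against chronic nephropathy samples, 38.6% of 1.5-fold, 78.6% of 2-fold and 95.9% of 4-fold changes were recovered, and 8 of 155 called genes were unchanged ones. For tolerant against healthy samples the shares were 10, 47.2 and 76.6%, with 2 of 93, and for chronic nephropathy against healthy samples 17.1, 59.7 and 95.2%, with 6 of 120. A shifted list, that of NK cells, was called in each of the 3 comparisons, beside 0, 0 and 1 other lists. The cytotoxic and earlier tolerance lists were left out of that count. The simulated noise was independent between genes, whereas the correlation estimated in the NK cell list was 0.496. The self-test thus cannot show how often camera calls a list falsely in these data.

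To see whether any 2 arrays of a group held the same hybridisation, the spread of their difference was set against the spread of replicate spots within arrays. A repeat hybridisation would also carry labelling and array noise, so a ratio above 1 does not exclude one. By 2 scripted measures 0 of 121 pairs within groups lay under the noise. The lowest ratios to the noise were 1.23, 1.25, 1.32 and 1.86 by the first measure (median 5.04) and 1.68, 1.99, 2 and 2.49 by the second (median 5.66), so the 3 closest pairs stood well apart from the median pair and may hold repeats. The 27 arrays were kept separate because no pair lay under the noise by these 2 measures. An earlier comparison with a rougher estimate of the noise had placed 2 pairs under it. The choice was thus not fixed before the data were seen, and if some arrays are repeats the spread is understated. Averaging the 3 closest pairs became an added alternative.

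Alternatives tried were no background subtraction, the software's log ratios, median centring without loess, loess followed by Aquantile, the series matrix values, no filter on dim probes, detection on all 27 arrays and the mean of a gene's probes. Others changed the model: no batch term, slide or scan day as fixed or random blocks, each extraction batch alone, all 31 arrays, an intensity trend with robust eBayes, array weights, only the 2 groups compared, replicate numbers as blocks, and each healthy replicate left out. Added after seeing the data were a fit without scan day 4, scan days 4 and 6 alone, a fit without chronic nephropathy replicate 7, the 3 closest pairs averaged, and the exact two-sided permutation of list scores within scan days, with all arrays and with the closest pairs averaged. The fixed blocks of slide and scan day cannot be estimated against the healthy group, and random blocks were used there. Between the graft groups, the fixed block of scan day compares samples only within days 4 and 6. That of slide compares them only within the 3 slides that held both groups. Coded scan days and slides were taken from the file headers and file names.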

Results

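Gene expression was measured in blood mononuclear cells of kidney graft recipients and of healthy people on 2-colour oligonucleotide arrays. On each array the blood RNA was labelled red (Cy5) and hybridised together with a common reference labelled green (Cy3), a pool of 21 human cell lines. The series held 31 arrays. Of these, 16 came from tolerant recipients (operational tolerance is the term for a graft that keeps working without immunosuppressive drugs), 10 from recipients whose graft had chronic injury, called the chronic nephropathy group here, and 5 from healthy people without a transplant. All 3 groups were together on 27 arrays of a single design, with 12 tolerant, 10 chronic nephropathy and 5 healthy samples. The other 4 tolerant samples were on a second design that held no other group, and they entered none of the 3 main fits. Values are log2 of red over green, so a difference between groups is a difference in blood RNA against the same reference.

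The red signal was well above background for 36.6 to 79.9% of the probes on the tolerant arrays, for 41.1 to 77.8% on the chronic nephropathy arrays and for 23.6 to 38.2% on the healthy arrays. This share followed the scan day. On the 11 arrays of scan days 2 and 4 it was between 23.6 and 45.1%, and on the other 16 arrays between 64.1 and 79.9%. All 5 healthy arrays were scanned on day 2, which held no graft array, so a difference of the healthy group from either graft group cannot be told apart from that day. Tolerant and chronic nephropathy arrays were scanned together on day 4, with 3 and 3 arrays, and on day 6, with 5 and 2 arrays. The first extraction batch held scan days 1 to 3 and the second held days 4 to 6, and the batch was a term of each fit. In the first batch the tolerant arrays were all scanned on day 1 and the chronic nephropathy arrays all on day 3, so group and scan day cannot be told apart there. The number of arrays, above all the 5 healthy ones, limits the precision of every value.

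**Figure D1:**
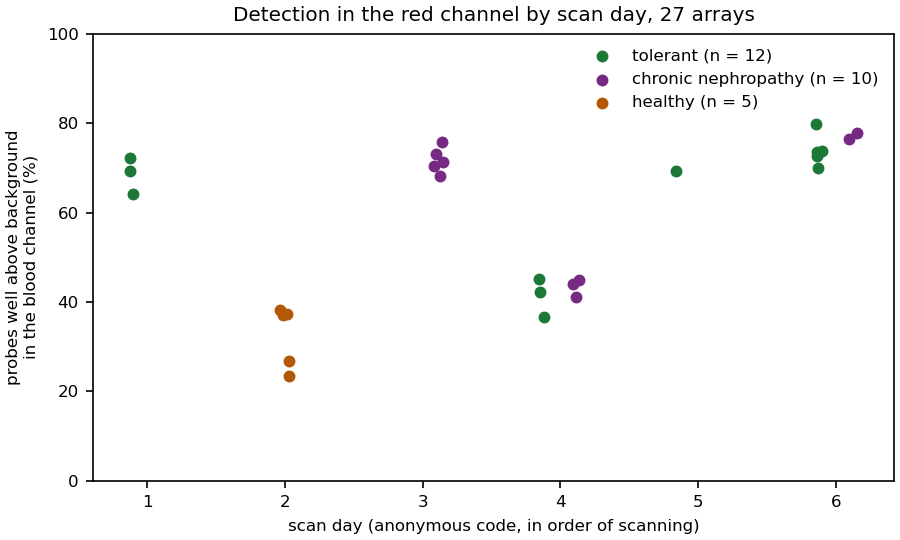
Share of probes well above background in the blood (red) channel, in percent, for each of the 27 arrays of the main design against the coded scan day, with 1 point per array coloured by group. The healthy arrays, at 23.6 to 38.2%, and the 6 graft arrays of scan day 4, at 36.6 to 45.1%, lay below the other arrays.

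Tolerant and chronic nephropathy samples were compared to ask which blood transcripts go with a graft kept without drugs rather than with chronic graft injury. Genes of NK cells, cytotoxic lymphocytes, B cells and plasma cells were higher as groups in the tolerant samples, and genes of red cell precursors were lower. With an estimated correlation only the plasma cell call held (adjusted p = 0.00267), while those of NK cells (0.111), cytotoxic lymphocytes (0.242), B cells (0.298) and red cell precursors (0.482) were lost, and the B cell median was -0.17 in the first extraction batch alone. With the batch as a term the largest median was that of the NK cell list (surface receptors, adaptors and chemokines of natural killer cells), 1.29 on the log2 scale over 15 genes, 13 of them higher. The ranking changed with the block: with slide as a fixed block the medians of the earlier tolerance genes (1.39) and B cells (1.29) exceeded that of NK cells (1.05). That block compares the groups only within the 3 slides that held both. KLRF1, an activating receptor of NK cells, stood at 4.53 ± 0.79 (SD, n = 12) in tolerant and at 2.14 ± 0.87 (SD, n = 10) in chronic nephropathy samples. No single gene passed the test over all genes, so the values of single genes below are given as values.

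In the NK cell list, KLRB1, a lectin-like receptor, had a fitted log2 difference of 2.22 ± 0.49 (SE), SH2D1B, a signalling adaptor of NK receptors, 2.31 ± 0.52, and KLRF1 2.28 ± 0.42. Their limma adjusted p over all genes were 0.156, 0.16 and 0.0712, and 13 of the 15 NK genes passed when adjusted over the list alone. The list was called by camera (adjusted p = 1.44e-11), and the call was lost at an adjusted p = 0.111 with an estimated correlation. Its median was 1.20 with scan day as a block, 1.27 within scan day 4 and 1.39 within scan day 6. The block value rests on the arrays of days 4 and 6, the only days with both groups. The day 4 difference in the mean list score leaned on chronic nephropathy replicate 7: it was 1.24 with it and 0.70 without it, and the list median over all arrays without it was 1.09 (adjusted p = 4.53e-09). In an exact two-sided permutation of list scores within those days (420 reassignments, 8 tolerant and 5 chronic nephropathy samples), the NK score differed by 1.23 (exact p = 0.00952, adjusted over 26 lists 0.0495). That call was lost when the closest pairs of arrays, 2 of them within those days, were averaged to leave 7 and 4 samples (exact p = 0.04, adjusted 0.208). No list of the 26 passed there, and the smallest exact p, that of plasma cells, was 0.01 (adjusted 0.13), the smallest that 100 reassignments can give. The NK score of the 4 tolerant arrays of the second design was not higher on the probes shared by both designs. It lay at -0.30 ± 0.29 (SD, n = 4) from the mean of the 10 chronic nephropathy arrays, against 1.28 for the 12 tolerant arrays of the main design. Design, software version and group cannot be told apart there. Such an offset, here and for the lists below, thus shows neither presence nor absence of a group difference.

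The cytotoxic lymphocyte list, made of granule proteins and other genes of killer T and NK cells, had a median log2 difference of 1.08 over 17 genes, 15 of them higher (camera adjusted p = 5.14e-08). GZMB and GZMA, proteases of the killing granules, differed by 1.72 ± 0.34 (adjusted p = 0.0735) and 1.68 ± 0.36 (adjusted p = 0.123), and FGFBP2, a gene of mature killer cells, by 2.18 ± 0.43 (adjusted p = 0.0735). Adjusted over the list alone, 8 genes passed. With an estimated correlation the adjusted p was 0.242. The median was 1.12 with scan day as a block, 1.34 within day 4 and 0.97 within day 6, but 0.52 (adjusted p = 0.147) in the first extraction batch alone. It was 0.41 with the scanner software's log ratios (0.27 relative to all genes, adjusted p = 0.00111) and 0.45 with the authors' processed values (0.28 relative to all genes, adjusted p = 0.00125). The permutation within scan days gave an exact p = 0.0333 (adjusted 0.0963). Without chronic nephropathy replicate 7 the day 4 score difference fell from 1.20 to 0.59 and the list median over all arrays was 0.69 (adjusted p = 1.22e-05). The 4 arrays of the second design lay at -0.71 ± 0.72 from the chronic nephropathy mean.

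B cell genes had a median log2 difference of 0.81 over 20 genes, 17 of them higher (camera adjusted p = 2.07e-06). BANK1, an adaptor of the B cell receptor, differed by 1.37 ± 0.35, FCRL2, a receptor of memory B cells, by 0.93 ± 0.25, and PNOC, a neuropeptide precursor transcribed in B cells, by 0.82 ± 0.24, with adjusted p of 0.233, 0.278 and 0.294. Adjusted over the list alone, 11 genes passed, and with an estimated correlation the list's adjusted p was 0.298. A list of 10 genes reported for tolerance in earlier kidney studies shares CD79B, TCL1A, MS4A1, FCRL1, FCRL2 and PNOC with the B cell list and SH2D1B with the NK list. Its median was 0.87 with all 10 genes higher (camera adjusted p = 2.05e-07, adjusted p = 0.127 with an estimated correlation), and 7 genes passed when adjusted over the list alone. That median was 0.48 (adjusted p = 0.377) in the first extraction batch alone, where the call was lost, and 0.50 (adjusted p = 0.00142) without scan day 4. The B cell median differed between subsets of the arrays: it was 1.1 with scan day as a block, 1.42 within day 4 and 0.71 within day 6, but -0.17 (adjusted p = 0.446) in the first extraction batch alone, where group equals scan day, and 0.32 (adjusted p = 0.0859) without scan day 4. The permutation within scan days gave an exact p = 0.00476 (adjusted 0.031) for both lists, and the 4 arrays of the second design lay at -0.67 ± 0.05 for B cells and at -0.34 ± 0.18 for the earlier tolerance genes.

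Plasma cell genes, which serve antibody assembly and secretion, gave the list call that also held with an estimated correlation. Their median log2 difference was 0.37 with all 14 measured genes higher (camera adjusted p = 5.88e-10, adjusted p = 0.00267 with an estimated correlation). JCHAIN, the joining chain of secreted antibodies, differed by 1.73 ± 0.33 (adjusted p = 0.0712), TNFRSF17, a survival receptor of plasma cells, by 1.30 ± 0.30 (adjusted p = 0.16), and DERL3, a factor of protein disposal in the secretory pathway, by 0.60 ± 0.14 (adjusted p = 0.196). Adjusted over the list alone, 8 genes passed. The median was 0.47 with scan day as a block, 0.50 within day 4, 0.43 within day 6 and 0.43 in the first extraction batch alone, and the permutation within scan days gave an exact p = 0.00238 (adjusted 0.031), the smallest it can give. On the second design, where design and group cannot be told apart, the 4 tolerant arrays lay 0.50 ± 0.37 above the chronic nephropathy mean, all 4 of them above it.

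**Figure D2:**
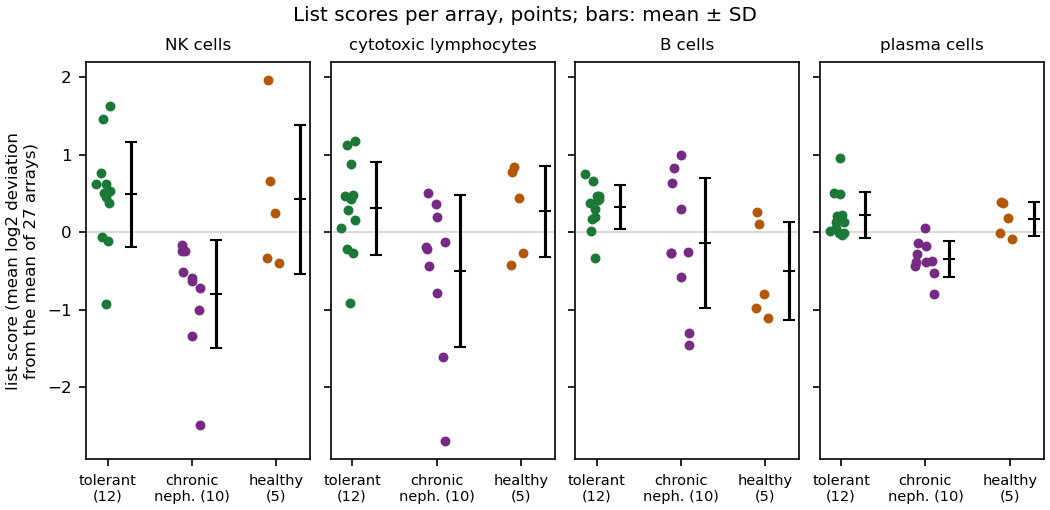
Scores of 4 gene lists (mean log2 deviation of a list's genes from their mean over the 27 arrays) in each sample, by group, with 1 point per array and the mean ± SD beside the points. In all 4 panels the tolerant mean lay above the chronic nephropathy mean, and the points of the groups overlapped.

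Smaller shifts were called by camera in other lists. Dendritic cell genes had a median of 0.52 (adjusted p = 1.71e-05, 0.129 as adjusted p with an estimated correlation), with CLEC4C, a receptor of plasmacytoid dendritic cells, at 0.51 ± 0.15 and CLEC10A, a lectin of myeloid dendritic cells, at 1.03 ± 0.39. Genes of oxidative phosphorylation encoded in the nucleus had a median of 0.28, with 41 of 44 higher (adjusted p = 1.21e-11, 0.111 as adjusted p with an estimated correlation); NDUFB3, a subunit of complex I, differed by 0.65 ± 0.17 and UQCRQ, a subunit of complex III, by 0.59 ± 0.15. Cytosolic ribosomal protein genes had a median of 0.36, with 41 of 46 higher (adjusted p = 5.83e-11, 0.246 as adjusted p with an estimated correlation), and the median was 0.14 with scan day as a block. Heat shock genes had a median of 0.30 (adjusted p = 0.0326, 0.192 as adjusted p with an estimated correlation), 0.13 with scan day as a block, the permutation within scan days gave an exact p = 0.00476 (adjusted 0.031), and HSPE1, a mitochondrial chaperonin, differed by 0.54 ± 0.15. Pan T cell genes had a median of 0.26 (adjusted p = 0.00401, 0.482 as adjusted p with an estimated correlation), with the T cell surface proteins CD2 at 0.79 ± 0.32 and CD5 at 0.57 ± 0.24. Costimulation and checkpoint receptors had a median of 0.35 (adjusted p = 0.00643, 0.433 as adjusted p with an estimated correlation) and of 0.06 with scan day as a block, where the call was lost (adjusted p = 0.148), and BTLA, an inhibitory receptor of lymphocytes, differed by 1.18 ± 0.38. Adjusted over the list alone, 12 genes passed in the oxidative phosphorylation list, 13 higher and 1 lower in the ribosomal list, 2 each in the dendritic and costimulation lists, 1 in the heat shock list and 0 in the pan T cell list. In the exact permutation within scan days the dendritic (adjusted p = 0.0619), oxidative phosphorylation (0.149), ribosomal (0.414), pan T cell (0.414) and costimulation lists (0.59) did not pass. Without chronic nephropathy replicate 7 the heat shock (0.0977), pan T cell (0.108) and costimulation calls (0.0589) of camera were lost.

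Lists called in the other direction were those of red cell precursors, with a median of -0.60 and 15 of 16 genes lower (camera adjusted p = 0.000207, 0.482 as adjusted p with an estimated correlation), and of neutrophils with their precursors, with a median of -0.10 (adjusted p = 0.0204, 0.482 as adjusted p with an estimated correlation). SELENBP1, a gene of late red cell precursors, differed by -1.21 ± 0.49 and TRIM58, which acts in their loss of the nucleus, by -1.47 ± 0.64, but with no batch term by -0.87 (adjusted p = 0.645) and -0.63 (adjusted p = 0.877). The red cell median was -0.31 with no batch term (adjusted p = 0.0292), -0.33 with median centring (adjusted p = 0.00527), -0.70 with scan day as a block, -0.14 within day 4 and -1.04 within day 6. ELANE, the elastase of neutrophil granules, differed by -0.47 ± 0.20 and LCN2, an iron-binding granule protein, by -0.67 ± 0.26; the neutrophil median turned to 0.03 with the authors' processed values, but stayed at -0.14 relative to all genes, whose median moved to 0.17 (adjusted p = 0.00125). The neutrophil median was -0.42 with scan day as a block, -0.06 within day 4 and -0.69 within day 6. The neutrophil call was lost with median centring (adjusted p = 0.13). In the first extraction batch alone no list was called lower, so the red cell and neutrophil calls were both lost there. In neither list did a gene pass when adjusted over the list alone, and neither passed the exact permutation within scan days (adjusted p 0.39 and 0.414).

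**Figure D3:**
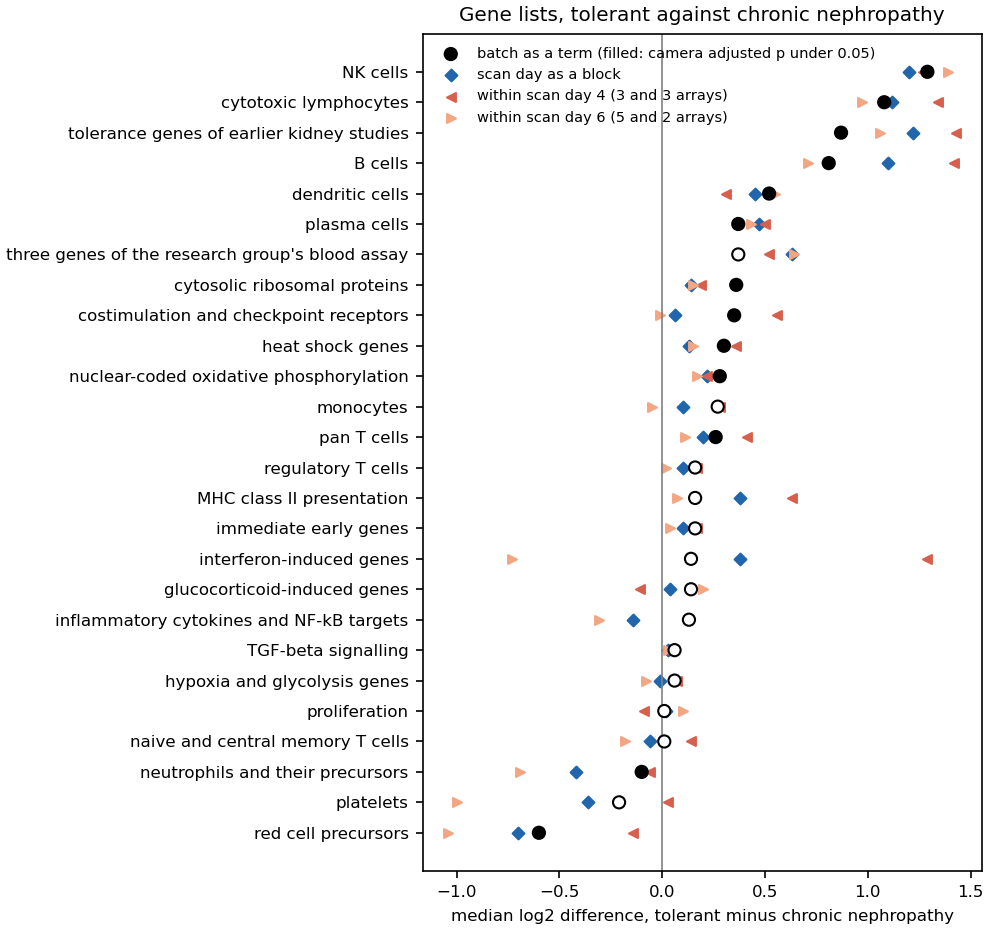
Median log2 difference, tolerant minus chronic nephropathy, for the 26 gene lists with the batch as a term (circles, filled where the camera adjusted p was under 0.05), with scan day as a block (diamonds) and within scan days 4 and 6 (triangles). The NK cell list lay at 1.29, 1.20, 1.27 and 1.39, while the interferon list lay at 1.29 within day 4 and at -0.73 within day 6.

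The other lists were not called between the graft groups as fitted. With scan day as a block camera called 3 of them, MHC class II presentation (median 0.38, adjusted p = 0.00452), interferon-induced genes (0.38, adjusted p = 0.0179) and platelets (-0.36, adjusted p = 0.00345), none of which passed the exact permutation within scan days (adjusted p 0.0516, 0.581 and 0.687). Without scan day 4 the interferon list was called in the other direction (-0.36, adjusted p = 0.0481) and the MHC class II median was -0.12 (adjusted p = 0.51). As fitted, the medians were 0.01 for naive and central memory T cells, 0.16 for regulatory T cells, 0.27 for monocytes, -0.21 for platelets, 0.14 for interferon-induced genes, 0.13 for inflammatory cytokines and NF-kB targets and 0.16 for immediate early genes. They were 0.06 for hypoxia and glycolysis genes, 0.14 for glucocorticoid-induced genes, 0.06 for TGF-beta signalling (where the test leaned the other way), 0.16 for MHC class II presentation and 0.01 for proliferation, where the mean was -0.02. Proliferation genes were called up with no background subtraction (0.18, adjusted p = 0.0321), the scanner software's log ratios (0.50, adjusted p = 0.000772) and the authors' processed values (0.43, adjusted p = 0.00125). Platelet genes were called down with the same 3 (medians -0.42, -0.19 and -0.16, adjusted p 0.00649, 0.00299 and 0.00225), but had a median of 0 with no batch term (adjusted p = 0.772). With median centring camera called regulatory T cells (0.31, adjusted p = 0.0391) and monocytes (0.24, adjusted p = 0.0163) up. The 3 genes of a blood assay of the research group had a median of 0.37 (camera adjusted p = 0.182). CYP1B1, a monooxygenase induced through the aryl hydrocarbon receptor, differed by 0.99 ± 0.30 (adjusted p = 0.303) and passed when adjusted over the list alone. BNC2, a zinc finger protein, differed by 0.37 ± 0.26 (adjusted p = 0.601) and KLF6, an immediate early transcription factor, by -0.11 ± 0.26 (adjusted p = 0.897). The KLF6 value turned positive under 5 other settings, the first extraction batch alone among them. These 3 genes may have been chosen on these same samples, so their list is not independent evidence.

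Among genes lower in the tolerant samples, the smallest p belonged to ARHGEF37 (-1 ± 0.19, adjusted p = 0.0712), ARHGEF12 (-0.75 ± 0.14, adjusted p = 0.0712) and MARK3 (-0.76 ± 0.17, adjusted p = 0.16). MARK3 encodes a protein kinase of cell polarity. In limma, 0 of 16640 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.0712. At an unadjusted p under 0.05 there were 1880 genes, where 832 would be found by chance on average. That excess is not beyond chance by much: with labels reassigned within batches, 5 of 100 splits, the real one included, had at least as many, and the highest other had 3391. Scan day as a block gave 12 genes, array weights 191 and the 2 graft groups fitted alone 8. Camera called 13 of the 26 lists, 11 up and 2 down, fry called 8, camera with an estimated correlation 1, and the exact permutation within scan days 5, or 0 with the closest pairs averaged.

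Tolerant samples were compared with healthy ones to see how blood under operational tolerance differs from blood of people without a graft. The largest differences lay in genes of acute cell activation, which were far lower in the tolerant samples. Single genes such as CXCR1 and CCR2 were higher, although both were not well above background on most healthy arrays. Among immediate early genes, transcribed within minutes of a stimulus, 21 of 25 fell and 1 rose, with a list median of -2.22. Among inflammatory cytokines and NF-kB targets, 16 of 21 fell and none rose, with a median of -2.94. IL1B, the precursor of interleukin-1 beta, stood at 1.61 ± 0.83 (SD, n = 12) in tolerant and at 7.12 ± 2.03 (SD, n = 5) in healthy samples, a fitted log2 difference of -5.38 ± 0.64 (SE).

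Within the activation lists, CD69, an early activation antigen of lymphocytes, fell to a log2 difference of -5.29, NR4A2, an immediate early nuclear receptor, to -3.32, and DUSP2, a phosphatase of MAP kinases, to -2.92. The chemokines CCL3 and CCL4 lay at -4.97 and -4.14, and NFKBIA and TNFAIP3, feedback inhibitors of NF-kB, at -4.75 and -4.40. IL6, a cytokine of the acute phase, lay at -5.42 and G0S2, an inhibitor of fat breakdown induced on activation, at -5.76. Each of these 9 genes lay below the healthy median in all 12 tolerant samples, and their adjusted p ranged from 7.5e-09 for NR4A2 to 1.02e-05 for IL6. CD83, a surface marker of activated dendritic cells, lay at -4.20 (adjusted p = 6.85e-09), the smallest p of the comparison. The immediate early call held with an estimated correlation (adjusted p = 0.0148), and that of the inflammatory list did not (adjusted p = 0.11). The healthy samples spread widely in some of these genes: IL6 stood there at 4.06 ± 2.79 and NR4A3, another receptor of this family, at 4.38 ± 3.06. Inflammatory list scores had an SD of 1.52 in healthy, 0.40 in tolerant and 0.35 in chronic nephropathy samples. The fit shares 1 spread over the groups, so errors and adjusted p of such genes against healthy samples are too small.

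Among the genes with the largest rise, CXCR1, a receptor of interleukin-8, rose by 4.58 ± 0.48 on the log2 scale, NLRP12, an inhibitor of inflammatory signalling in myeloid cells, by 4.11 ± 0.56, and CCR3, a chemokine receptor of eosinophils, by 4.08 ± 0.58. CCR2, which draws monocytes to tissue, rose by 3.85 ± 0.45, KCNE3, a potassium channel subunit, by 3.81 ± 0.33, and MME, a peptidase of neutrophils, by 3.79 ± 0.74. CXCR1, KCNE3 and MME were well above background on 1 of the 5 healthy arrays and NLRP12, CCR3 and CCR2 on 2 of them, so the sizes of these differences are uncertain. The monocyte list was called up, with a median of 1.23 and 5 of 21 genes higher (camera adjusted p = 0.0216, 0.964 as adjusted p with an estimated correlation), among them MNDA at 2.41, CSF1R at 2.39, CD14 at 1.83 and TYROBP at 1.23. The neutrophil list had a median of 0.59 and was not called (adjusted p = 0.168), although 6 of its 19 genes rose, such as CXCR2 at 2.81 and FCGR3B at 2.47. PADI4, an enzyme of neutrophils, was not well above background on any healthy array and lay at least 1.01-fold higher in the tolerant samples.

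B cell genes rose as well, 10 of 20, with a list median of 1.13 (camera adjusted p = 0.00154, 0.964 as adjusted p with an estimated correlation). CD79B, a chain of the B cell receptor, rose by 2.67 ± 0.57, FCRLA, an Fc receptor-like protein, by 2.48 ± 0.53, and CD72, a B cell coreceptor not well above background on any healthy array, by at least 1.3-fold. The list of earlier tolerance genes had a median of 1.29 with 6 of 10 higher (adjusted p = 0.0162, 0.964 as adjusted p with an estimated correlation), among them TCL1A, a gene of naive B cells, at 3.51 ± 0.91 and TLR5, the flagellin receptor, at 2.31 ± 0.58. CD79B, FCRLA and CYP1B1 were well above background on 2 of the 5 healthy arrays and TLR5 on 1. MHC class II presentation genes had a median of 0.95 with 5 of 12 higher (adjusted p = 0.0216, 0.964 as adjusted p with an estimated correlation), for example IFI30, a lysosomal reductase, at 1.40 ± 0.42. Cytosolic ribosomal protein genes were called down, with a median of -0.26, 10 of 46 lower and 3 higher (adjusted p = 0.0162, 0.964 as adjusted p with an estimated correlation). RPL11 of this list, a protein of the large subunit, had a fitted difference of -1 ± 0.22, but of -0.15 (adjusted p = 0.764) with no batch term. CYP1B1 rose by 2.20 ± 0.43 (adjusted p = 0.000651), while KLF6 at -0.79 and BNC2 at -0.35 did not pass, and the list of these 3 genes was not called (median -0.35, adjusted p = 0.964).

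In limma 4068 of 16640 genes differed between tolerant and healthy samples, 2573 higher and 1495 lower, so that 63.2% were higher. That share was 82.4% of 6328 genes with the scanner software's own log ratios and 87.8% of 7027 genes with the authors' processed values, which moved the median of all genes from 0.115 to 0.467 and 0.591. It was 56.8% of 1461 among the genes well above background on all 27 arrays. With scan day as a random block 2232 genes were called, and within the first extraction batch, with 3 tolerant and 5 healthy arrays, 1517. Camera called 7 lists, 4 up and 3 down, and 1 with an estimated correlation. Without healthy replicate 4 the monocyte, MHC class II and earlier tolerance lists were no longer called (medians 0.60, 0.55 and 1.09, adjusted p 0.545, 0.205 and 0.1), and without replicate 5 the ribosomal list was not (median -0.25, adjusted p = 0.0792). With no batch term the B cell, earlier tolerance and MHC class II lists were not called (adjusted p 0.102, 0.0909 and 0.0909).

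**Figure D4:**
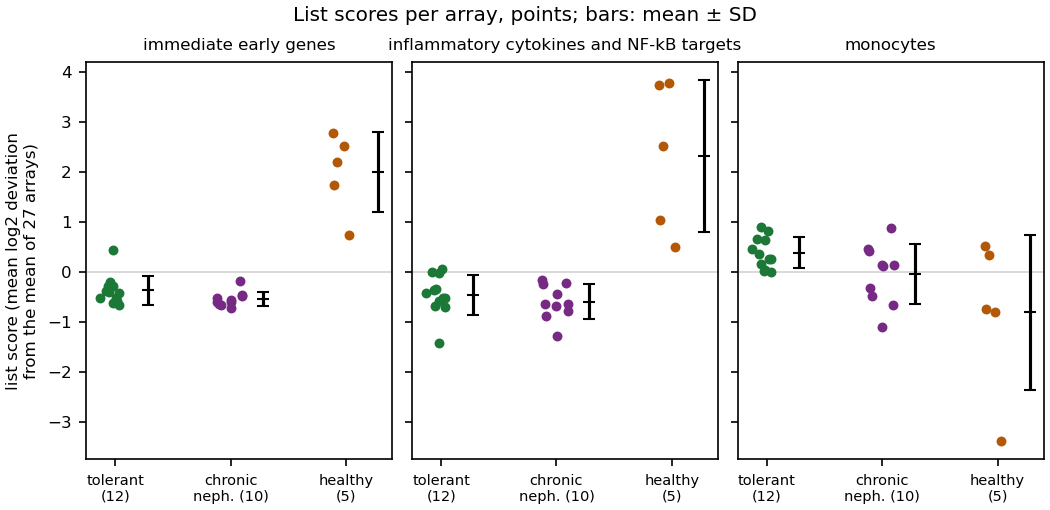
Scores of 3 gene lists (mean log2 deviation of a list's genes from their mean over the 27 arrays) in each sample, by group, with 1 point per array and the mean ± SD beside the points. In the immediate early and inflammatory panels the healthy samples lay above the graft groups, which overlapped each other.

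Chronic nephropathy samples were compared with healthy ones to see how blood under chronic graft injury differs from that of people without a graft. Activation genes again lay far below the healthy level. NK cell and ribosomal protein genes also lay below it, calls that were both lost with an estimated correlation (adjusted p = 0.656), and the NK call was absent with 3 other scalings. Of the immediate early genes 23 of 25 fell, with a list median of -2.39, and of the inflammatory genes 17 of 21 fell, with a median of -2.80. KLRB1 stood at 5.25 ± 1.32 in chronic nephropathy and at 8.20 ± 0.88 in healthy samples with a fitted difference of -3.04 ± 0.65.

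Among activation genes, CD69 fell to a log2 difference of -6.50, CCL3 to -5.87, CCL4 to -5.61, IL1B to -5.41 and NFKBIA to -4.92. JUN, a subunit of the AP-1 transcription factor, lay at -3.78, DUSP2 at -3.08, CD83 at -4.64 and G0S2 at -6.65. All 9 genes lay below the healthy median in all 10 samples, with adjusted p from 1.32e-10 for CD83 to 6.07e-07 for IL1B. Here too the shared spread makes the adjusted p too small for genes in which the healthy samples spread more widely. The immediate early call held with an estimated correlation (adjusted p = 0.0145), and that of the inflammatory list did not (adjusted p = 0.131). Genes that rose included FRAT2, an activator of Wnt signalling, at 3.52 ± 0.38, CXCR1 at 4.34 ± 0.45, NLRP12 at 4.01 ± 0.52, CCR2 at 3.59 ± 0.42, KCNE3 at 3.47 ± 0.31 and MME at 3.46 ± 0.69. All but FRAT2 were well above background on at most 2 of the 5 healthy arrays, so the sizes of these differences are uncertain. The neutrophil list was called up, with a median of 0.88 and 7 of 19 genes higher (camera adjusted p = 0.0143, 0.656 as adjusted p with an estimated correlation), among them CXCR2 at 2.73 and FCGR3B at 2.35, in a fraction from which Ficoll removes most neutrophils. That call was absent with median centring and in the first extraction batch alone.

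The NK cell list had a median of -1.46, with 5 of 15 genes lower and 1 higher (camera adjusted p = 0.00347, 0.656 as adjusted p with an estimated correlation). Besides KLRB1, IL2RB, a chain of the interleukin-2 receptor, lay at -1.79 ± 0.39, KLRF1 at -1.97 ± 0.56 and XCL2, a chemokine of NK cells, at -1.94 ± 0.56. The NK call was absent with no background subtraction (median -0.70, adjusted p = 0.153), with the scanner software's log ratios (median -0.39, adjusted p = 0.163) and with the authors' processed values (median -0.29, adjusted p = 0.123). Of the cytotoxic genes 3 of 17 fell, FGFBP2 at -2.19, GZMA at -1.73 and GZMB at -1.67, with no call for the list (median -0.39, adjusted p = 0.0846). Plasma cell genes had a median of -0.29 with 5 of 14 lower, such as JCHAIN at -1.84 ± 0.44, and no call (adjusted p = 0.0611). They were called down with the scanner software's log ratios (adjusted p = 0.0134) and the authors' processed values (adjusted p = 0.0169). Dendritic cell genes were called down with a median of -0.40 (adjusted p = 0.0373, 0.656 as adjusted p with an estimated correlation), a median that turned to 0.49, or 0.12 relative to all genes, with the scanner software's log ratios. The dendritic call was absent with the same 3 scalings (adjusted p 0.279, 0.232 and 0.18) and without healthy replicate 5 (adjusted p = 0.0952).

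Ribosomal protein genes were lower in 23 of 46 and higher in 3, with a median of -0.50 (camera adjusted p = 7.3e-07, 0.656 as adjusted p with an estimated correlation). RPL11 lay at -1.46 ± 0.21 and RPL7, also of the large subunit, at -1.34 ± 0.22, but at -0.89 (adjusted p = 0.0358) and -0.90 (adjusted p = 0.0195) with no batch term. Oxidative phosphorylation genes were called down with 15 of 44 lower and 3 higher (adjusted p = 0.00785, 0.656 as adjusted p with an estimated correlation). Their median was -0.09 and their mean -0.33, and with arrays centred on the median in place of loess the median was 0.01, or -0.14 relative to all genes, with no call (adjusted p = 0.0603). COX6C, a subunit of complex IV, lay at -2.09 ± 0.34 and NDUFA6, a subunit of complex I, at -1.52 ± 0.25. B cell genes had a median of 0.59 with 4 of 20 higher, among them CD79B at 1.57 ± 0.54, and no call (adjusted p = 0.112), and earlier tolerance genes had a median of 0.64 (adjusted p = 0.496). CYP1B1 rose by 1.21 ± 0.40 (adjusted p = 0.0247), KLF6 at -0.67 and BNC2 at -0.72 did not pass, and the 3-gene list was not called (median -0.67, adjusted p = 0.626).

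**Figure D5:**
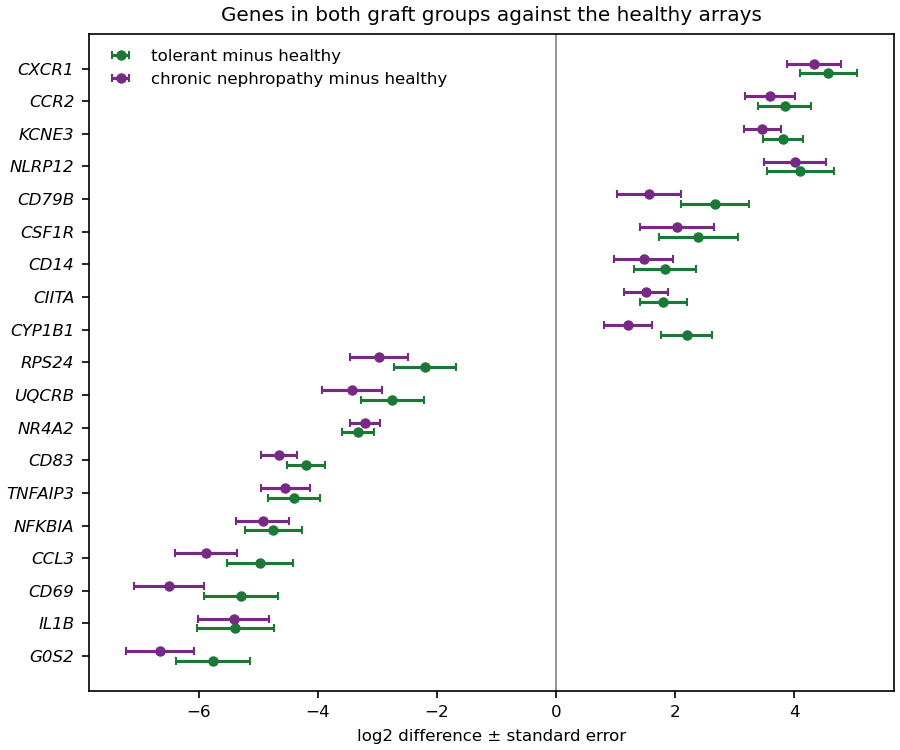
Fitted log2 difference ± SE of 19 genes in tolerant minus healthy and in chronic nephropathy minus healthy samples. CD69 lay at -5.29 and -6.50 and IL1B at -5.38 and -5.41, while CXCR1, KCNE3, CCR2, NLRP12, CD79B and CYP1B1 were well above background on at most 2 of the 5 healthy arrays.

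In limma 4722 of 16640 genes differed between chronic nephropathy and healthy samples, 2706 higher and 2016 lower, so that 57.3% were higher. That share was 74% of 6783 genes with the scanner software's log ratios and 79.5% of 7124 genes with the authors' processed values, which moved the median of all genes from 0.1 to 0.369 and 0.463. Among the 5588 genes well above background on all 27 arrays it was 43.6% of 1874, with 817 higher and 1057 lower. The majority turned to lower there. With scan day as a random block 2474 genes were called, and within the first extraction batch, with 5 arrays of each group, 2983. Camera called 7 lists, 1 up and 6 down, and 1 with an estimated correlation. With no background subtraction it called 10, 5 up and 5 down. The balance of directions thus depended on the scaling. Without healthy replicates 2 and 4 in turn, 11 and 12 lists were called.

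Both graft groups were compared with the same 5 healthy arrays, so their differences share the chance values of those arrays. They also share any effect of scan day 2, which held all healthy arrays and no graft array. Neither the simulation nor the splits below can remove or imitate such an effect. Across genes, which are not independent replicates, the 2 sets of log2 differences correlated at r = 0.916, and 87.2% of genes had the same sign. Unchanged groups simulated against the same healthy arrays gave a mean r of 0.747 (range 0.218 to 0.932) and the same sign for 77.2% of genes (range 54.1 to 87.9%), ranges that hold the observed values of both. With separate subsets of the healthy arrays for the 2 comparisons, r lay between 0.438 and 0.824 over 10 splits. The covariance was 0.486 against 0.0814 in the simulation, a difference of 0.405. The shuffling put mostly graft residuals in the healthy places, while the real healthy arrays spread more widely in the activation lists. The simulation may thus understate what the 5 healthy arrays share by chance. Called higher in both were 2044 genes and called lower in both 1313, where independent lists would share 423 and 182, the split healthy arrays gave 575 to 1012 and 391 to 807, and the simulation gave 0 of each. These shared counts are from a fit with missing spots filled by fitted values, which calls slightly more genes.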

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

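Samples far from the others of their group were looked for in the chronic nephropathy and healthy groups, and the tolerant group was not tested. Such a sample was found in 30 of 332 tests of list scores and genes, where chance gives 16.6, about 1 in 20 groups. The value given for each is the gap of the farthest sample to its nearest neighbour as a share of the group's range. Among list scores in the chronic nephropathy group a sample far from the others was found for NK cells (0.49), dendritic cells (0.50), immediate early genes (0.50), glucocorticoid-induced genes (0.70) and proliferation (0.49). In the healthy group it was found for naive and central memory T cells (0.75), regulatory T cells (0.84), dendritic cells (0.75), platelets (0.71) and proliferation (0.71). The healthy group has 5 samples, so a single array weighs on each of these means.

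Among single genes, a chronic nephropathy sample lay far from the others for CCL3 (0.65), CCL3L3 (0.78), CLEC10A (0.66), CLEC4C (0.64), FRAT2 (0.47), GZMB (0.51), HBM (0.58), HSPA6 (0.56) and LCN2 (0.54). The same was found there for NFKBIA (0.59), NR4A2 (0.56), PER1 (0.53), PGK1 (0.52) and SMAD3 (0.65). A healthy sample lay far from the others for CDC20 (0.80), FCRL2 (0.77), FECH (0.80), MNDA (0.83), SELENBP1 (0.75) and TGFBR2 (0.90).

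The plasma cell score showed a signal in data outside the comparisons: the 4 tolerant arrays of the second design lay 0.50 ± 0.37 (SD, n = 4) above the mean of the 10 chronic nephropathy arrays, all 4 above the mean and 2 above the highest of them. Heat shock genes, at 0.26 ± 0.20, had the same numbers, and the inflammatory, immediate early, ribosomal, glucocorticoid and 3-gene assay scores also lay above the mean on all 4 arrays. The array design and the group cannot be told apart there, since the second design held no other group.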

How the results depend on the processing

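The main limits were 5 healthy arrays scanned on a day of their own, a batch term on which the healthy differences rest because all healthy arrays were in the first extraction batch, and a red signal that on 11 of 27 arrays was well above background for 23.6 to 45.1% of probes. That share was low although the median red signal was not. The median was 291 to 532 on healthy, 134 to 333 on tolerant and 131 to 327 on chronic nephropathy arrays. For genes not well above background the size of a difference is uncertain, and absence on the healthy arrays was not shown. Why few probes were well above background on these arrays was not tested. For PADI4 and CD72 the difference the background allows was at least 1.01-fold and 1.3-fold, and for TGIF2 no rise was bounded. Loess followed by Aquantile leaves log ratios unchanged by construction and gave the same counts. A fixed block for slide or scan day was not run against healthy samples, where it cannot be estimated.

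Genes that differ between tolerant and chronic nephropathy samples, 0 as fitted, numbered 2 with no background subtraction (TNFRSF17 and JCHAIN), 3 with the software's log ratios and 3 with the series matrix values (ARHGEF37, JCHAIN and TNFRSF17 in both), and 3 with detection on all 27 arrays (JCHAIN, GZMB and FGFBP2). They numbered 1 with no batch term (KLRF1), 12 with scan day as a fixed block (3 higher, 9 lower), 2 in the first extraction batch alone (ARG1 and SPATA8), 2 in the second alone (LOC442239 and ARHGEF37), 8 with only the 2 groups compared, 191 with array weights (87 higher, 104 lower) and 30 with scan day 6 alone (1 higher, 29 lower), the last chosen after seeing the data. Genes that differ between tolerant and healthy samples, 4068 as fitted, numbered 6328 with the software's log ratios (5215 higher, 1113 lower), 7027 with the series matrix values (6168 higher, 859 lower), 1461 with detection on all 27 arrays, 2232 with scan day as a random block, 1517 in the first batch alone and 2406 with only the 2 groups. For chronic nephropathy against healthy samples, 4722 as fitted, they numbered 6783 with the software's log ratios (5019 higher, 1764 lower), 7124 with the series matrix values (5661 higher, 1463 lower), 1874, 2474, 2983 and 2817 under the same further settings. Detection on all 27 arrays tested 5588 genes and 22 lists, so its counts fall by construction. Leaving out 1 healthy replicate gave 3117 to 4650 and 3666 to 5200 genes.

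Called lists between the graft groups, 13 as fitted, numbered 7 with detection on all 27 arrays, 5 in the first batch alone, 1 with an estimated correlation, 8 with fry, 5 when permuted within scan days and 0 when permuted with the closest pairs averaged, where the smallest exact p that can be reached is 0.01. For tolerant against healthy samples, 7 as fitted, they numbered 2 with detection on all 27 arrays, 4 with no batch term, 4 in the first batch alone, 1 with an estimated correlation and 5 to 8 without 1 healthy replicate. For chronic nephropathy against healthy samples, 7 as fitted, they numbered 4 with detection on all 27 arrays, 13 with no batch term, 13 with all 31 arrays, 1 with an estimated correlation and 8 to 12 without 1 healthy replicate, 11 without replicate 2 and 12 without replicate 4. Between the graft groups the pan T cell, heat shock and costimulation calls were absent with no background subtraction (adjusted p 0.0917, 0.0912 and 0.0583), the software's log ratios (0.314, 0.1 and 0.213) and the series matrix values (0.27, 0.127 and 0.241). Against healthy samples, the tolerant monocyte and MHC class II calls were absent with the software's log ratios (adjusted p 0.222 and 0.2), the B cell call in the first batch alone (0.103), and the chronic nephropathy neutrophil call with median centring (0.0674) and in the first batch alone (0.061). The calls of NK and plasma cells between the graft groups, and of immediate early and inflammatory genes against healthy samples, were kept under every scaling. Without scan day 4, and with the 3 closest pairs averaged, both added after seeing the data, 0, 3757 and 5125, and 0, 3638 and 4227 genes were called. With those pairs averaged, 11 lists were called between the graft groups, without neutrophils (adjusted p = 0.11) and heat shock genes (0.0534). Of those pairs 2 lay within the scan days used in the permutation, which would leave fewer independent samples there. The 2 chronic nephropathy arrays of scan day 6 formed such a pair. The values and gene count of that day alone may thus rest on a single chronic nephropathy sample. Without chronic nephropathy replicate 7, also chosen after seeing the data, 0, 4014 and 5007 genes and 11, 7 and 8 lists were called. Between the graft groups the pan T cell (adjusted p = 0.108), heat shock (0.0977) and costimulation calls (0.0589) were then absent and platelets were called down (-0.51, 0.000768). The cause of these changes was not tested.

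Direction reversed for 7 genes, BNC2 in 2 comparisons, and the cause was not tested except where the scaling shows it. Between tolerant and healthy samples, TNFRSF18 was 0.05 with the software's log ratios and 0.18 with the series matrix values, and BNC2 was 0.06, 0.18 and, without healthy replicate 3, 0.12 (lowest -0.61, without replicate 2). Between chronic nephropathy and healthy samples, IL2RA was 1.77 and 1.52 and CD86 0.03 and 0.12 with those 2 sets of values. These scalings moved the median of all genes to 0.467 and 0.591 for tolerant and to 0.369 and 0.463 for chronic nephropathy samples, so TNFRSF18, BNC2 and CD86 stayed below it and only IL2RA also reversed relative to all genes. Between the graft groups, KLF6 was 0.18 with the mean of its probes, 0.13 with slide as a fixed block, 0.13 in the first batch alone, 0.05 with all 31 arrays and 0.20 with scan day 4 alone. In the first batch alone BNC2 was -0.04, CD247 -0.09 and FECH 0.34.

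Replicate numbers of the labels as a block gave 4, 606 and 2937 genes, the 4 being OLFM4, FAM30A, IGH and LOC388588. Samples that shared a number correlated at r from -0.27 to 0.38 over 6 numbers, at 0.04 over 1 and from -0.09 to 0.20 over 5, over 0.1 in 2, 0 and 2 of them, and 0, 0 and 1 samples correlated best with their own number, so the numbers were not taken to pair samples.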

Other observations

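The tests of drugs, of scan day for the NK cell pattern and of the share of other cells were chosen after the results were seen. They thus describe the data and are not independent support. The other tests were chosen before their own values were seen. Against healthy samples, heat shock genes were not called as a list (median -0.02 in tolerant, -0.12 in chronic nephropathy). The chaperones HSPA1A and HSPA6 rose by 1.96 and 2.49 on the log2 scale in tolerant and by 2.07 and 2.19 in chronic nephropathy samples, while HSP90AA1 and HSPE1 lay at -1.30 and -1.02 in the latter. In the hypoxia and glycolysis list (medians 0.16 and 0.23, not called), PFKFB4 rose by 1.96 and 1.81 and PFKFB3, which makes the same glycolytic activator, lay at -1.93 and -2.24. Glucocorticoid-induced genes were not called (median 0.54 with a mean of 0.09 in tolerant, 0.32 with a mean of -0.11 in chronic nephropathy): PER1, a clock gene, lay at -1.68 and -1.96, SGK1, a kinase, at -1.5 in tolerant samples, and TSC22D3, a leucine zipper protein induced by glucocorticoids, rose there by 1.02. In TGF-beta signalling (medians -0.06 and -0.24, not called) ID2, an inhibitor of helix-loop-helix factors, lay at -1.28 and -1.41.

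Other lists not called in tolerant against healthy samples had medians of 0.28 for plasma cells, 0.00 for pan T cells, 0.01 for naive T cells, 0.25 for cytotoxic lymphocytes, 0.23 for NK cells (where the test leaned down), -0.08 for regulatory T cells and 0.04 for dendritic cells. They were -0.25 for platelets, 0.54 for red cell precursors, -0.65 for interferon-induced genes, -0.03 for costimulation receptors, -0.15 for proliferation and 0.17 for oxidative phosphorylation, where the mean was -0.04. In chronic nephropathy against healthy samples they were -0.26 for pan T cells, -0.15 for naive T cells, -0.22 for regulatory T cells, 0.72 for monocytes, 0.19 for platelets (mean -0.15) and 1.03 for red cell precursors. They were -0.85 for interferon-induced genes, 0.71 for MHC class II, -0.10 for costimulation receptors and -0.30 for proliferation. The T cell costimulator ICOS lay at -2.44 in chronic nephropathy samples and CD28 at -1.23, whereas TNFSF14, a costimulatory ligand, rose by 1.75 there and by 2.11 in tolerant samples.

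On the second design, the 3-gene assay score of the 4 tolerant arrays lay 0.74 ± 0.24 (SD, n = 4) above the mean of the 10 chronic nephropathy arrays, all 4 above the highest of them. Scores of immediate early genes lay there at 1.06 ± 1.57, of red cell precursors at -1.46 ± 1.72 and of platelets at -1.01 ± 0.46.

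The high activation genes of the healthy arrays were set against scan day, a low share of probes well above background, and drugs. Scan day cannot be excluded, since 0 graft arrays were scanned with the healthy ones. A low share of such probes was argued against as the cause. Graft arrays of scan day 4, which also had a low share, scored 0.11 ± 0.11 above those of days 5 and 6. This was less than 0.88, the part set in advance of the gap of 2.65 ± 0.51 between healthy and graft arrays. The healthy arrays also had a higher local red background than the day 4 arrays, which this test does not cover. In tolerant against healthy samples the immediate early median was -2.22 and the list score differed by -2.37 ± 0.37. In so far as operational tolerance means being off drugs, drugs as the only cause would not give this. The limit of that test was set after this median was seen, so it is not independent support. Handling of the blood before the RNA was made may also differ between the groups and was not tested.

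The higher NK, cytotoxic, B cell and plasma cell genes of tolerant samples were set against scan day and a lower share of other cells. The NK list kept a median of 1.27 within day 4 and 1.39 within day 6, which argued against scan day as the only cause. Its median of 1.20 with scan day as a block rests on the arrays of the same days and is no further check. The day 4 score difference fell from 1.24 to 0.70 without chronic nephropathy replicate 7, and 2 of the 3 closest pairs of arrays lay within days 4 and 6. The 2 chronic nephropathy arrays of day 6 formed such a pair, so the day 6 value may rest on a single sample of that group. The NK score rose over the pan T cell score by 0.93 ± 0.22, so these lymphocyte lists did not shift alike in these samples. Both list medians were known when this test was chosen, so its outcome was not open. On the 4 tolerant arrays of the second design the mean scores of NK cells, B cells and cytotoxic lymphocytes (-0.71 ± 0.72) were not higher. Design and group cannot be told apart there, so this does not settle whether the pattern was absent. Whether the pattern reflects tolerance, treatment or selection of recipients was not tested.

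Of 15120 windows of 10 neighbouring genes, the farthest from 0 lay on chromosome 12 at 1.01 and ran from CD69 to KLRK1, a region of lectin-like receptors of NK cells. The lowest window lay in a stretch of chromosome 19 that held zinc finger genes and KRT18P40 (-0.16), which is not a zinc finger gene. In that stretch 17 of 18 genes were lower in tolerant than in chronic nephropathy samples, with a median of -0.52, against 0.10 for 386 other zinc finger genes. ZNF708, ZNF714, ZNF493 and ZNF85, transcriptional repressors by family, differed by -1.04, -0.99, -0.91 and -0.82, named after their values were seen, and no biological explanation was tested. The low values were not confined to dim probes: the 7 members well above background on all 27 arrays had a median of -0.50 (quartiles -0.81 and -0.27). The stretch was chosen by its low medians in these same data. Neither this median nor the contrast with other zinc finger genes is independent of that choice. Chance was not excluded: 14 of 100 splits of the labels, the real one included, had a window at least as far from 0 as the lowest one at -0.64, and the farthest of another split was at 1.00.

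Labels were also reassigned within extraction batches. Between the graft groups 100 of 100 splits called at least 0 genes, which excludes nothing, and 5 of 100, the real one included, had at least 1880 genes at an unadjusted p under 0.05 (highest other 3391). For tolerant against healthy samples 1 of 56 splits, the real one, reached 4068 genes (highest other 1475), and for chronic nephropathy against healthy samples 1 of 100 reached 4722 (highest other 3732). These splits do not separate the group from the scan day of the healthy arrays.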
